A study of Mus musculus with 2 samples.

How the data were processed

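The data were H3K36me3 ChIP-seq peak lists from hearts of B6NCrl mouse embryos at embryonic day 15.5, 2 biological replicates in a single group. Per the labels, each replicate was a pool of hearts from embryos of both sexes, the fragments were 300 to 500 bp long, and the replicates were sequenced in 3 and 2 runs. The authors aligned the reads to mouse genome build mm10 and deposited a narrowPeak list for each replicate, a list called on the pooled reads, and a list of replicated peaks. The list of replicate 1 was derived from its alignments and 2 further files, and that of replicate 2 from its alignments and 1 further file, whose content the labels do not state. The peak caller, its threshold and the rule for a replicated peak were not given in the sources used here, and input control libraries were not analysed here. Every replicated peak was checked to be a pooled peak with the same values.

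In the deposited lists, each peak carries a display score from the peak caller. The deposited signal value is a ratio, the fold enrichment at the peak relative to the caller's background, and is the authors' value throughout. The deposited −log10 p-value and −log10 q-value of each peak grow with depth. The deposited summit offset is in bp from the start of the peak. The peak lists give no read counts, so the depth was unknown and no interval that needs it was computed. The README texts that came with the samples hold no measurements and were left out. Positions are 1-based and inclusive.

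Bases were counted after overlapping peaks of a list had been merged. Gene models were those of GENCODE mouse release 21 (vM21). Eligible genes were protein-coding, on chromosomes 1 to 19 or X, and spanned at least 2 kb (20176 genes). A gene was called marked when replicated peaks covered at least 10% of its span. Peaks on chromosome Y and on scaffolds were outside all tests. The genome was taken as the bases other than N of chromosomes 1 to 19 and X. Each base was assigned to the first that applied of promoter (within 1 kb of a transcription start), coding exon or 5′ untranslated region, 3′ untranslated region, intron and intergenic. Profiles along genes used 20 equal bins and flanks of 10 kb in bins of 1 kb, over marked genes of at least 10 kb. Domains were replicated peaks joined at gaps of up to 5 kb. Spans of annotated genes can overlap, and some models run over several others, so a gene can be counted as marked through peaks on its neighbour.

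Overlap between replicates counted peaks sharing at least 1 bp and was set against 100 random placements within the same chromosome and, separately, within its genes (one-sided permutation p). The correlation of signal was computed over replicated peaks with a peak in both replicate lists, without a p. Each of 20 gene lists was compared with 100000 random lists drawn from other eligible genes in the same of 20 bins of gene length (two-sided permutation test, Benjamini-Hochberg over 20 lists). The lists held genes of sarcomere and cardiomyocyte structure, cardiac transcription factors, cardiac calcium handling and ion channels, mitochondrial energy metabolism, epicardial, endothelial and endocardial, fibroblast and valve mesenchyme, smooth muscle, erythroid, macrophage and leukocyte, neuronal, neural crest and Schwann cell, liver, and lung and epithelial markers, skeletal muscle specific genes, noncardiac developmental transcription factors, housekeeping genes, cell cycle genes, H3K36 methylation writers, erasers and readers, and imprinted genes. Members that were absent from the annotation under that symbol, shorter than 2 kb or not protein-coding were left out. These were Tcap, Nppa and Nppb (sarcomere), Sox18 (endothelial), 6 globin genes (erythroid), Cd68, Apoa1, Cldn4, Myf6, Neurog1, Hoxc12, Whsc1 and Whsc1l1 (H3K36 methylation), and H19, Airn, Meg3, Rian, Mirg, Kcnq1ot1, Phlda2 and Zac1 (imprinted). Pairs of lists were compared by Fisher's exact test, adjusted over 4 comparisons. The replicate difference of a list was the mean covered share in replicate 1 minus that in replicate 2, tested against length-matched lists in the same way. Gene classes and the X chromosome were tested with matched genes too, the classes adjusted over 5. Genes are not independent replicates, so each p from a test over genes describes these peak lists and not a spread between embryos. Every error is an SD over the 2 replicate lists unless said otherwise.

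Lists, tests, alternatives and the rule for naming genes were written before the data were examined. Genes named by rule were the 10 genes of at least 10 kb with the highest covered share in the replicated list and at least 50% of that share in each replicate, the 5 genes with most covered bases, the 2 highest and the lowest member of each list (ties to the longer gene), the 5 genes of at least 10 kb with the largest difference between replicates in either direction, and Setd2. The alternatives were each replicate alone, the pooled list, a −log10 q of at least 5, other minimum covered shares (5%, 25% and 1 bp), no minimum gene length, peaks joined at 1 kb, no matching on length, the mean covered share in place of a count, spans without the first 1 kb, equal numbers of peaks, shares scaled to equal means, other overlap rules and other joining gaps.

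The list test was tested on simulated data. Covered bases differed from a base-by-base count in 0 of 5050 checks. A simulated list was called at an unadjusted permutation p under 0.05, a looser rule than the adjusted p used for the 20 fixed lists. Of 400 lists without an effect, 2.25% were called by the count of marked genes and 5.5% by the mean covered share. With 34.5% of simulated genes marked, lists of 25 genes were called in 28%, 38.5% and 100% of 200 trials when 20%, 50% and 80% of their members were marked, so a modest difference in a list of that size was often missed. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.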

Results

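Trimethylation of lysine 36 of histone H3 (H3K36me3), a histone mark laid down over the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing in hearts of mouse embryos of strain B6NCrl at embryonic day 15.5. The samples formed a single group of 2 biological replicates, separate pools of hearts from embryos of both sexes, with 78 embryos in replicate 1 and 62 in replicate 2. Replicate 1 was sequenced in 3 runs and replicate 2 in 2 runs. The deposited data were peak lists on mouse genome build mm10, called by the authors in each replicate and in the pooled reads, with a list of replicated peaks. The lists hold no read counts, so the depth of each library was unknown and no counting interval could be given for a peak. There was no other tissue, stage or treatment, and the comparisons below are between replicates, between positions along genes and between sets of genes. The series gave no purpose beyond the profiling itself.

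The mark was called over far more of the genome in replicate 1 than in replicate 2, and the weaker list lay largely inside the stronger one. Replicate 1 held 172818 peaks that covered 106 Mb, or 4.16% of the genome, and replicate 2 held 118477 peaks that covered 50.1 Mb, or 1.96%. The means were 145648 ± 38425 peaks and 78.3 ± 39.9 Mb (SD, n = 2). Of the replicate 2 peaks, 89.2% overlapped a replicate 1 peak by at least 1 bp, and 45.6% of the replicate 1 peaks overlapped a replicate 2 peak. Among the strongest 10000 peaks of each list, 97.1% of those of replicate 1 and 99.5% of those of replicate 2 overlapped a peak of the other list. The shared bases came to 42.7 Mb, a Jaccard index of 0.375. When replicate 2 peaks were placed at random within the genes of the same chromosome, 12.8% of them overlapped a replicate 1 peak on average, and the one-sided permutation p was 0.0099, the smallest that 100 placements can give. At a −log10 q of at least 5 only 9843 replicate 2 peaks were left against 58158 of replicate 1, and the Jaccard index was 0.127.

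The authors' fold enrichment per peak, relative to the background of each list, was similar in height between replicates, with a median of 2.96 in replicate 1 and 2.87 in replicate 2 (2.91 ± 0.0628, SD, n = 2). Over 70447 replicated peaks with a peak in both lists, the log2 fold was higher in replicate 1 by 0.26 on average, with an SD of 0.38 across peaks. Pearson's r of the log2 fold was 0.387 and Spearman's rho was 0.353. These are correlations across regions, which are not independent replicates. With the −log10 p of each peak, which grows with depth, Pearson's r was 0.532. The replicated list kept 95072 of the 153587 pooled peaks (61.9%). They covered 89.4 Mb, or 3.49% of the genome, and had a median width of 631 bp against 259 bp for the pooled peaks that were not kept. Of the kept peaks 74.1% overlapped a peak in both replicate lists and 24.2% overlapped a replicate 1 peak only.

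H3K36me3 peaks in the embryonic heart lay mostly inside genes, with few at their starts. Of the bases in replicated peaks, 95.7% were within or at the promoter of a protein-coding gene (95.4% ± 0.449 in the replicate lists, SD, n = 2), against 41.1% of the genome. Introns held 75.6% of the peak bases, 2.05 times their share of the genome. Coding exons and 5′ untranslated regions held 12.1%, an enrichment of 8.77 times, and 3′ untranslated regions held 7.66%, an enrichment of 6.0 times. Promoters, within 1 kb of a transcription start, held 0.334%, or 0.209 times their genomic share, and intergenic sequence held 4.33%, or 0.0735 times. The spread between replicates was small beside these differences: the share was 75.4% ± 1.34 in introns, 12.2% ± 1.66 in coding exons and 0.326% ± 0.0119 in promoters (SD, n = 2).

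Coverage rose along the gene body. Over 5517 marked genes of at least 10 kb, replicated peaks covered 1.49% of the first of 20 equal bins and 57.8% of bin 18. The last bin was covered to 50.1%. The last 5 bins were covered 3.92 times as much as the first 5, with ratios of 3.49 and 4.17 in replicates 1 and 2 (3.83 ± 0.485, SD, n = 2). The first 1 kb upstream of the start was covered to 0.899%. Past the annotated gene end, coverage was 37.3% in the first 1 kb and 13.2% in the tenth. The tenth 1 kb upstream of the start was also covered to 13.2%, so the level at that distance was not particular to gene ends.

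**Figure D1:**
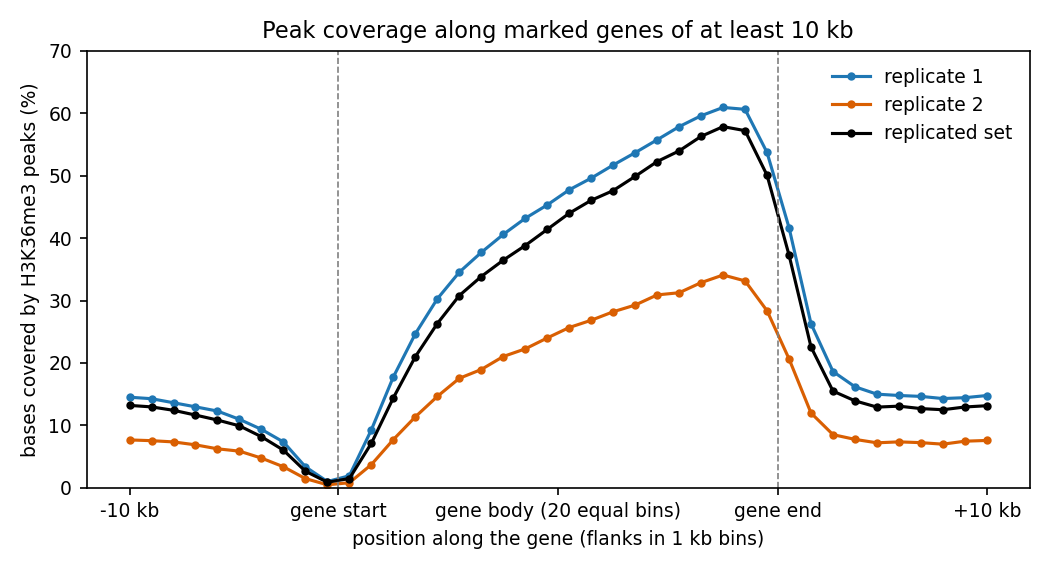
Share of bases covered by peaks (percent, vertical axis) along 20 equal bins of the gene body and 10 kb on either side in bins of 1 kb (horizontal axis), over 5517 marked protein-coding genes, with one line for the replicated list and one for each replicate list. Coverage in the replicated list rises from 1.49% in the first bin to 57.8% in bin 18 and falls past the gene end.

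Within marked genes, exons were covered more than introns, with the exception of first exons. In 7180 marked genes the replicated peaks covered 52.7% of exon bases and 28.9% of intron bases, a ratio of 1.82 (1.84 ± 0.199 in the replicate lists, SD, n = 2). First exons were covered to 2.63%, middle exons to 69.6% and last exons to 54.6%. The replicate means were 2.23% ± 1.29, 58.4% ± 20.6 and 44.9% ± 18.5 (SD, n = 2), so the distance between first and later exons was larger than the spread between replicates. Exons and introns were matched on neither position along the gene nor gene length, and coverage rose along the gene, so the ratio is descriptive. No test was applied to these profiles, since neighbouring bases are not independent.

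Joined at gaps of up to 5 kb, the replicated peaks formed 15339 domains with a median length of 4528 bp, of which 4910 were at least 10 kb long and 23 at least 100 kb. The last count was 67 with replicate 1 peaks alone and 16 with replicate 2 peaks alone. The longest, of 196 kb, lay in Fbn2, which encodes the extracellular matrix protein fibrillin-2 (chromosome 18, 58007464 to 58203956), and 57.8% of it was covered (60.7% in replicate 1 and 33.2% in replicate 2). Domains of 154 kb in Vps13d, a lipid transfer protein gene, and 152 kb in Herc2, a ubiquitin ligase gene, came next. Titin, the giant spring protein of the sarcomere, carried a domain of 147 kb within Ttn and another of 121 kb that reached into Plekha3. A domain of 131 kb ran over Mtor, Angptl7 and Exosc10, and one of 119 kb lay in Ryr2, the calcium release channel of heart muscle. The others among the longest 10 lay over Hectd4 and Trafd1, over Fry, and over Ncor1 and Ttc19. No domain of at least 10 kb lay outside annotated genes, and 6 of at least 5 kb did, of which 5 followed within 5 kb of a gene end. Joining at 1 kb instead gave 35033 domains, 2504 of them at least 10 kb long and 1 at least 100 kb, and joining at 10 kb gave 102 of at least 100 kb.

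The genes covered most completely had varied functions. Sf3a1, a splicing factor gene, was covered over 92.1% of its span (chromosome 11, 4160350 to 4182541; 80.3% ± 13.7 in the replicate lists, SD, n = 2). Gpi1, a glycolytic enzyme gene, was covered to 90.8% (77.2% ± 18.0), the uncharacterised 1700109H08Rik to 90.3% (81.2% ± 15.4) and Ddb1, a DNA damage binding protein gene, to 90.2% (85.9% ± 7.21). Zfp110, a zinc finger gene, and Mybbp1a, a nucleolar regulator, were both covered to 89.5% (88.1% ± 1.59 and 76.7% ± 13.7). The condensin gene Ncapd2 and Glyr1, which encodes a nucleosome binding protein, were both covered to 88.8% (74.7% ± 15.1 and 76.0% ± 14.4). Prr12 followed with 88.6% (75.0% ± 16.8) and the RNA exosome gene Exosc10 with 88.4% (77.8% ± 14.2). Ttn had 211 kb in peaks, 75.8% of its span. Vps13d had 116 kb and Macf1, a cytoskeletal linker gene, 115 kb. Gm20388 and Fgfr2 had 408 kb and 163 kb in peaks, but their annotated spans of 4435 kb and 2961 kb run over many other genes, and only 9.19% and 5.51% of each was covered.

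Of 20176 protein-coding genes of at least 2 kb, 7180 (35.6%) were marked, meaning that replicated peaks covered at least 10% of the span. No base was covered in 10254 genes (50.8%), and at least 50% of the span was covered in 2165. The median marked gene was covered to 36.4%. Peaks of replicate 1 alone marked 8056 genes and those of replicate 2 alone 5390, and 5385 genes were marked in both. Averaged over all eligible genes, the covered share was 16.2% in replicate 1 and 8.26% in replicate 2 (12.2% ± 5.62, SD, n = 2).

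The strongest single peaks lay on zinc finger genes, which encode a large family of DNA binding repressors. The authors' fold was 11.9 at Zfp810 (chromosome 9, 22278035 to 22281196), 11.5 at Plec, a cytoskeletal linker gene (chromosome 15, 76170434 to 76184795), 11.4 at Zfp26 (chromosome 9, 20435708 to 20440684), 11.0 at Zfp606 (chromosome 7, 12483474 to 12495117) and 10.8 at Zkscan8 (chromosome 13, 21518744 to 21523075). All 5 had the summit in a coding part of the last exon. Of the 20 strongest peaks, 17 were in zinc finger genes and 16 had the summit in the last exon. These peaks were chosen after their values were seen.

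The question put to the fixed gene lists was whether genes of heart cells carried the mark more often than genes of equal length. Contractile genes of heart muscle did: 18 of 28 sarcomere and cardiomyocyte structure genes were marked, against 9.75 in length-matched random lists. Ttn was covered to 75.8% (59.4% ± 28.3 in the replicate lists, SD, n = 2) and Xirp1, an actin binding protein of heart muscle, to 60.5% (41.4% ± 20.6). The cardiac myosin genes Myh6 and Myh7 were covered to 50.6% and 18.6%, Mybpc3, which encodes a myosin binding protein, to 56.4%, and the troponin gene Tnnt2 to 43.1%. Replicated peaks covered no base of Actc1 and Myl7, a cardiac actin and an atrial myosin light chain gene, or of the X-linked Smpx, though replicate 1 peaks covered 21.4% of Actc1. Myh6, Myh7, Mybpc3, Tnnt2, Actc1 and Myl7 were chosen after their values were seen. The sarcomere result had an adjusted permutation p of 0.00303, and it depended on replicate 1 and on the minimum covered share. With replicate 2 peaks alone 11 genes were marked and the adjusted permutation p was 0.208, and with at least 25% of the span covered 11 were marked and it was 0.115, within a range of 8.9e-05 to 0.208 over 12 alternatives.

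Cardiac transcription factors and ion channels were not shown to be marked more often than matched genes at 10% covered. Of the cardiac transcription factors 9 of 25 were marked, against 8.25 in matched lists (adjusted permutation p = 0.943). Srf, a regulator of muscle genes, was covered to 54.1% (41.1% ± 17.6, SD, n = 2) and Mef2d, another muscle regulator, to 49.2% (42.0% ± 10.7). Tbx20 was covered to 43.8%, Gata6 to 41.0% and Gata4 to 8.74%. No base was covered in Tbx3, a regulator of the conduction system, or in Nkx2-5, Hand1 and Hand2, which act in early heart formation. Tbx20, Gata6, Gata4, Nkx2-5, Hand1 and Hand2 were chosen after their values were seen. Of calcium handling and ion channel genes 7 of 22 were marked, against 5.15 (adjusted permutation p = 0.522). With replicate 1 or replicate 2 peaks alone 10 and 2 were marked. When any covered base counted, 18 were marked and the list was above matched genes (adjusted permutation p = 0.0137, within 0.0137 to 1.00 over the alternatives). Atp2a2, the calcium pump of the sarcoplasmic reticulum, was covered to 83.5% (74.6% ± 12.7), Casq2, a calcium store protein, to 23.4% (24.2% ± 20.5), and the potassium channel gene Kcnd2 not at all.

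Genes of energy supply, general upkeep and growth were mostly marked. Of mitochondrial energy metabolism genes 34 of 37 were marked, of housekeeping genes 31 of 34 and of cell cycle genes 27 of 28. Uqcrc1 and Uqcrc2, subunits of the respiratory chain, were covered to 82.2% (71.6% ± 14.8, SD, n = 2) and 81.2% (70.7% ± 13.8), and the creatine kinase gene Ckmt2 was not covered. The translation factor genes Eif4g2 and Eef2 were covered to 85.9% (81.3% ± 3.40) and 82.0% (80.1% ± 3.33), and Ubc, a ubiquitin gene, to 5.52%. Top2a, a topoisomerase gene of dividing cells, was covered to 85.5% (69.8% ± 18.4), Rrm1, which supplies nucleotides, to 77.4% (65.4% ± 13.4), and the X-linked DNA polymerase gene Pola1 not at all. Matched lists held 15.1, 12.8 and 11.1 marked genes, and the permutation p was 2e-05 for each of these lists (1e-04 adjusted over 20 lists), the smallest that 100000 random lists can give.

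Enzymes and readers of H3K36 methylation were themselves marked, 18 of 22 against 8.24 in matched lists (adjusted permutation p = 0.000286). Kdm4a, a demethylase gene, was covered to 82.9% (71.4% ± 14.1, SD, n = 2), the reader gene Brpf1 to 73.6% (64.6% ± 10.3) and the reader gene Phf19 to 2.39%. Setd2, the trimethylating enzyme, was covered over 45.7% of its span (chromosome 9, 110532597 to 110618633; 38.9% ± 13). Imprinted genes, of which 1 parental copy is silent, were not shown to differ from matched genes, 7 of 20 against 6.63 (adjusted permutation p = 1). Nnat was covered to 69.5% (64.2% ± 13.7), Igf2r to 59.7% (49.5% ± 21.2) and Usp29 not at all.

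Markers of endothelium and epicardium were marked less often than matched genes, and those of fibroblasts and smooth muscle were not shown to differ from them. Of fibroblast and valve mesenchyme markers 6 of 24 were marked, against 9.06, and of smooth muscle markers 6 of 14, against 5.17 (adjusted permutation p = 0.329 and 0.930). The matrix gene Fn1 was covered to 71.5% (57.2% ± 18.9, SD, n = 2), Vim, an intermediate filament gene, to 52.5% (46.8% ± 15), Smtn, a smooth muscle cytoskeleton gene, to 58.3% (48.3% ± 18.0) and the smooth muscle actin gene Acta2 to 40.1% (27.4% ± 13.6), while Ddr2 and Mylk were not covered. Endothelial and endocardial markers were marked less often than matched genes, 3 of 24 against 8.45 (adjusted permutation p = 0.0276). Notch1, a receptor of valve and trabecular development, was covered to 27.3% (18.3% ± 11.9), Eng, a vascular coreceptor gene, to 25.4% (18.5% ± 13.2) and Vwf not at all. No endothelial gene was marked with replicate 2 peaks alone and 4 were with replicate 1 peaks alone. This call ended when 25% of the span had to be covered, with 2 genes marked, and when any covered base counted, with 12 marked. Epicardial markers had 1 of 17 marked, against 5.54 (adjusted permutation p = 0.0254). Krt18, a keratin gene, was covered to 10.5% (8.81% ± 4.59), Tbx18, a regulator of the epicardium, to 4.69% (5.86% ± 6.0) and Bnc2 not at all. With replicate 1 peaks alone the epicardial list had 2 marked genes and an adjusted permutation p of 0.0521, within 0.00193 to 0.0521 over the alternatives, and with replicate 2 peaks alone it had 0.

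Only 1 of the listed genes of blood, nerve, liver, lung and skeletal muscle was marked, and 6 globin genes were too short to be tested. Of macrophage and leukocyte markers 1 of 19 was marked, against 6.07 (adjusted permutation p = 0.0182), and this call ended with replicate 2 peaks alone (p = 0.122) and without a minimum gene length, where 2 were marked (p = 0.0590; 0.00225 to 0.122 over the alternatives). The gene marked at 2 kb or more was Cx3cr1, covered to 19.6% (15% ± 6.07, SD, n = 2). Its annotated span (chromosome 9, 119901616 to 120069879) contains the marked heart muscle gene Xirp1. Xirp1 held 5.96 kb of the 32.9 kb covered in the Cx3cr1 span, so most of the coverage lay elsewhere in that span. Csf1r, a macrophage growth factor receptor gene, was covered to 6.74% (4.89% ± 3.52) and Pax5 not at all. No gene was marked in the lists of erythroid (14 genes), neuronal (24), neural crest and Schwann cell (14), liver (24), lung and epithelial (19), skeletal muscle specific (23) and noncardiac developmental transcription factor genes (34). The best covered members were Sptb with 2.44% (3.6% ± 3.89) and Epb42 with 1.94% (2.46% ± 0.966), red cell skeleton genes, Slc17a7, a glutamate transporter gene, with 7.58% (5.65% ± 1.39), Erbb3, a receptor gene of Schwann cells, with 1.93% (5.56% ± 4.28), Serpinc1, the antithrombin gene, with 1.16% (2.34% ± 1.48) and Etv5, a lung branching factor, with 6.95% (7.72% ± 3.41). Replicated peaks covered no base of Ank1, Nrxn3, Cdh19, Cps1, Trp63, Ryr1, Pax7, Pax2 and Pax8. Matched lists held between 5.33 and 10.5 marked genes, and the adjusted permutation p lay between 1e-04, for the noncardiac transcription factors, and 0.00303.

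Sarcomere genes were marked more often than skeletal muscle specific genes, and cardiac transcription factors more often than noncardiac developmental ones. The share of marked genes was 64.3% for sarcomere genes and 0% for skeletal muscle specific genes (Fisher's exact test, two-sided, adjusted over 4 comparisons, p = 2.3e-06). Cardiac transcription factors were at 36% and noncardiac ones at 0% (Fisher's exact p = 0.000325). The cardiac factors were marked about as often as length-matched genes (9 against 8.25), and the noncardiac ones less often (0 against 10.5). This difference therefore does not show the cardiac factors above genes in general. Fibroblast markers were at 25% and liver markers at 0% (Fisher's exact p = 0.0292), and with replicate 2 peaks alone the difference was 16.7 percentage points with p = 0.146 (7.6e-07 to 0.146 over the alternatives); the call also ended at a −log10 q of at least 5 and at 25% covered. Endothelial and neuronal markers, at 12.5% and 0%, were not told apart (Fisher's exact p = 0.234), though they were when any covered base counted, with a difference of 45.8 points (Fisher's exact p = 0.000699, within 0.000699 to 1 over the alternatives). With replicate 2 peaks alone the sarcomere difference was 39.3 points and the transcription factor difference 24.0 points.

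**Figure D2:**
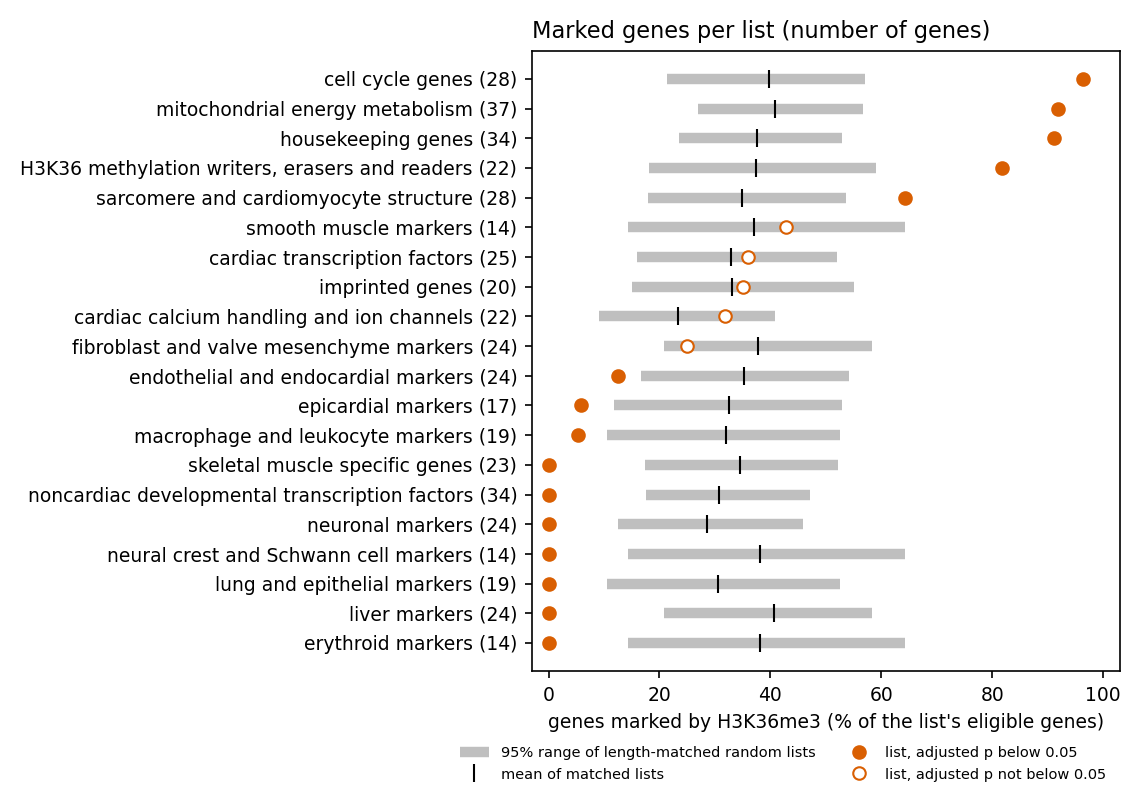
Share of genes marked (percent, horizontal axis) in each of the 20 fixed lists (vertical axis), with points for the lists, filled where the adjusted p was below 0.05, and grey bars and ticks for the 95% range and mean of length-matched random lists. Mitochondrial, housekeeping and cell cycle genes lie far above their ranges, and the lists of skeletal muscle, liver and noncardiac transcription factor genes lie at 0%.

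Gene lists differed in how far their covered share was lower in replicate 2 than in replicate 1. The sarcomere list was covered to 32.2% on average in replicate 1 and 10.2% in replicate 2 (21.2% ± 15.6, SD, n = 2). The shares were 53.9% and 36.9% for housekeeping, 55.0% and 34.0% for mitochondrial and 58.5% and 34.7% for cell cycle genes. Some lists with little coverage also had far lower shares in replicate 2. The shares were 5.26% and 1.48% for endothelial, 1.63% and 0.438% for epicardial and 1.30% and 0.275% for erythroid markers. Neuronal markers went the other way, with 0.194% and 0.276%, and noncardiac transcription factors had 0% in both. In percentage points, the differences of 22.0 for sarcomere, 23.7 for cell cycle, 21 for mitochondrial, 20.0 for H3K36 methylation and 17.0 for housekeeping genes were above those of length-matched lists (permutation p adjusted over 20 lists of at most 8.9e-05). They stayed so with the same number of strongest peaks in each replicate, at 17.6, 20.9, 17.4, 16.5 and 14.3 points (adjusted permutation p of at most 0.000133). These lists were better covered than matched lists, and a difference in points grows with coverage, so these tests do not set the lists apart from other genes of their level. Each replicate's shares were also scaled to the same mean over all eligible genes, which removed the 1.96 times higher mean of replicate 1. Sarcomere genes still had more in replicate 1, by 12.2 points against 0.0337 in matched lists (adjusted permutation p = 0.000133). Smooth muscle markers and cardiac transcription factors were also positive, at 5.11 and 3.88 points, without a call (adjusted permutation p = 0.0713 and 0.113). The matched lists had like length and not like coverage, so the sarcomere value alone does not set these genes apart from others of their coverage. The cell cycle, mitochondrial, H3K36 methylation and housekeeping lists changed sign, to between −18.4 and −4.62 points. A share cannot pass 100% and 1 factor was used for every gene, so no direction is read from this for lists that were already well covered. In 10 lists with little coverage the unscaled difference was smaller than in matched lists (adjusted permutation p of at most 0.0378), which follows from their coverage in the same way, and not after scaling (adjusted permutation p of at least 0.502). Each of these values compares 1 library with 1 other.

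**Figure D3:**
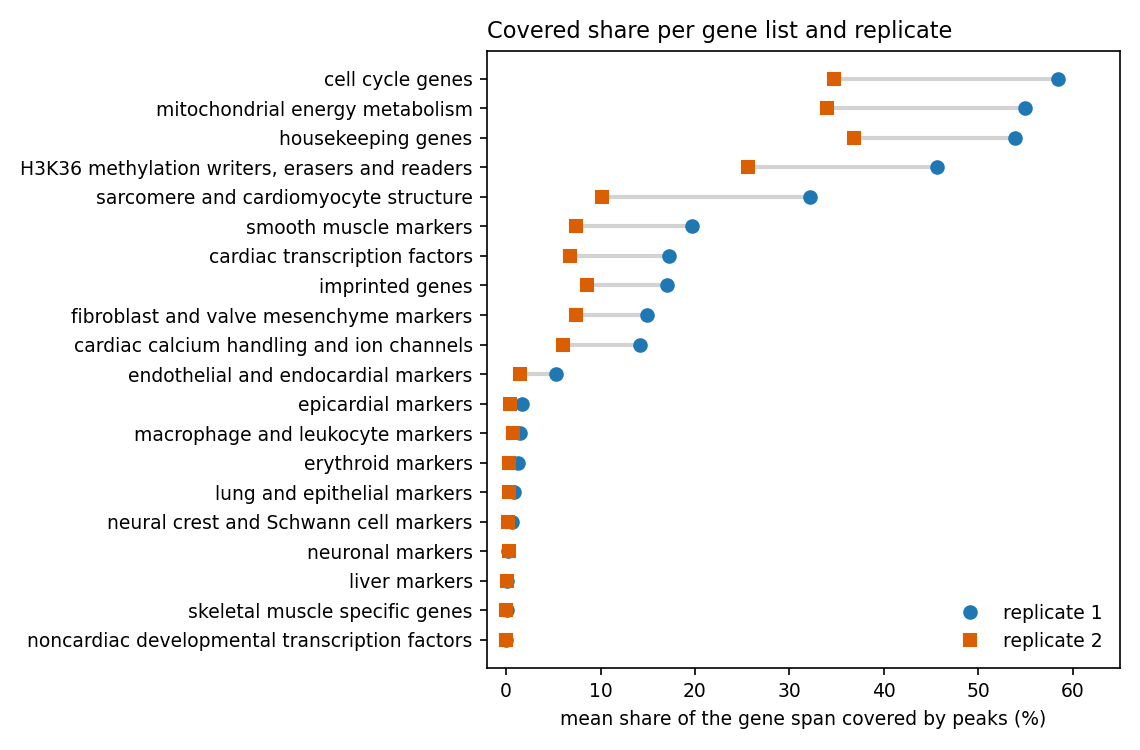
Mean covered share (percent, horizontal axis) of each gene list (vertical axis) in the peak list of replicate 1 and in that of replicate 2, one point for each. Sarcomere genes fall from 32.2% to 10.2% and housekeeping genes from 53.9% to 36.9%.

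Among single genes of at least 10 kb, the excess of replicate 1 reached 51.5 percentage points in Crat, which encodes a carnitine acetyltransferase of mitochondria (72.5% and 21% covered). Phb, a mitochondrial scaffold gene, followed with 48.3 points, then Med16, a subunit of the Mediator complex, with 47.5, Ercc2, a helicase gene of DNA repair, with 46.7, and the oxidoreductase gene Pyroxd1 with 46.5. The opposite differences were small. Plppr3, a membrane protein gene of neurons, had a covered share in replicate 1 minus replicate 2 of −4.96 points, the phospholipase gene Pla2g3 of −3.79, Champ1, a chromosome alignment gene, of −3.23, Adamts4, a matrix protease gene, of −2.97 and the adaptor gene Grap of −2.65.

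No chemosensory receptor gene was marked, and zinc finger genes were marked more often than matched genes. None of 1037 olfactory receptor genes and none of 269 vomeronasal receptor genes was marked, while 34.6% and 40.4% of matched genes were. Of 393 zinc finger genes named Zfp, 255 (64.9%) were marked against 39.7% of matched genes. Genes of a single exon were marked in 14 of 321 cases (4.36%), against 24.7% of matched genes, and with replicate 1 peaks alone the share was 8.41%. The permutation p was 2e-05 for each of these classes, the smallest that 100000 random sets can give, and 2.5e-05 after adjustment over 5 classes. Histone genes were picked by the start of their symbol, which does not separate replication-dependent genes from histone variants. They were marked in 3 of 11 cases of at least 2 kb (27.3%, against 32.6%, adjusted permutation p = 0.983). When genes of any length were counted, 3 of 90 were marked.

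Peaks covered little of the X chromosome. Of 791 X-linked genes 74 were marked (9.36%), against 35.4% of length-matched autosomal genes (95% range 32.2% to 38.7%). Its replicate mean of 4.51 ± 3.77 kb in peaks for each Mb (SD, n = 2) was below those of all 19 autosomes, which ran from 22.1 ± 11.5 kb on chromosome 14 to 53.7 ± 25.7 kb on chromosome 11. Among autosomes the share of marked genes ran from 27.6% on chromosome 14 to 46.5% on chromosome 8. The X-linked genes covered most were Flna, an actin crosslinker gene, with 69.2% (60.7% ± 11.4, SD, n = 2), Maged1, an adaptor gene of cell death signalling, with 58.8% (42.5% ± 16.4), and the histone demethylase gene Kdm5c with 58.8% (48.7% ± 16.8). These 3 genes were chosen after their values were seen. The permutation p for the X chromosome was 2e-05, the smallest that 100000 random sets can give. It was the same with either replicate alone, where 16.3% (replicate 1) and 4.30% (replicate 2) of X-linked genes were marked. Genes are not independent replicates, so this p describes these peak lists.

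**Figure D4:**
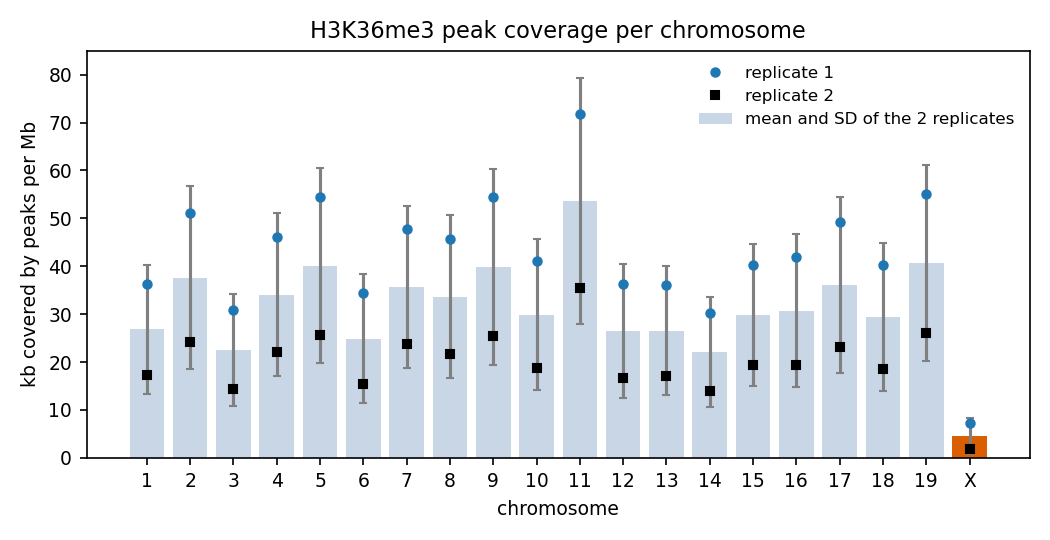
Peak coverage (kb in peaks for each Mb of chromosome, vertical axis) on chromosomes 1 to 19 and X (horizontal axis), with points for the replicate lists and bars with error bars for their mean and SD (n = 2). The X chromosome lies at a mean of 4.51 kb for each Mb and the autosomes between 22.1 and 53.7.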

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

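No test was applied to the values in this part, so none was chosen after a result was seen, and no biological explanation was tested. The peaks on chromosome Y and on scaffolds lay outside the measurements compared in the report, and the pooled peaks that were not kept lay outside its gene comparisons except as an alternative. The replicated list held 6 peaks on chromosome Y, which the tests left out. One lay from 259200 to 259417 with a fold of 4.34, and the other 5 lay close together between 90739068 and 90745840 with folds of 1.23 to 2.46. None overlapped an annotated gene. A further 4 replicated peaks lay on unplaced or unlocalised scaffolds, the strongest with a fold of 8.32, and none of these overlapped an annotated gene. The pooled list held 58515 peaks that were not in the replicated list, 38.1% of it. They covered 17.1 Mb, with a median width of 259 bp and a median fold of 2.28, against 631 bp and 2.97 for the kept peaks. Of the peaks that were not kept, 70.2% overlapped a replicate 1 peak only, 10.1% a replicate 2 peak only, 18.4% neither and 1.33% both.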

How the results depend on the processing

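All alternatives were planned ones, and 373 of 424 were taken as the same result. A test was the same if it kept its direction and side of the threshold, and a measured share or ratio if it moved by less than its spread. A count was the same if it stayed within a fixed factor of the main value. That rule is loose: all 9 alternatives for the number of marked genes passed it, at 4940 to 9922. Of 240 tests of a list under an alternative, 221 gave the same call and direction. Of the 20 lists, 11 had the same call and direction in all 12 alternatives: 4 of the 5 marked more often than matched genes (all but the sarcomere list), 7 of the 10 marked less often, and none of the 5 that were not called. Overlap between replicates stayed above random placement in the alternatives run, but its size did not hold: the Jaccard index ranged over 0.127 to 0.407 and the share of replicate 1 peaks in replicate 2 over 14.3% to 57.0%, both lowest at a −log10 q of at least 5. The number of marked genes ranged over 4940 to 9922, and the marked share of X-linked genes over 4.30% to 16.3%. In the alternatives run, X-linked genes were marked less often than matched autosomal genes. The ratio of the last to the first 5 bins ranged over 3.52 to 4.34 and that of exons to introns over 1.70 to 1.84. The cause of the changes was not tested unless stated.

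With 1 replicate left out, the number of marked genes ranged over 11 to 23 for sarcomere genes, 2 to 10 for calcium handling and ion channels, 0 to 2 for epicardial, 3 to 7 for smooth muscle and 1 to 1 for macrophage markers. With replicate 2 alone the sarcomere and macrophage lists were not called and calcium handling and smooth muscle genes reversed without a call, and with replicate 1 alone the epicardial list was not called. The fibroblast minus liver difference ranged over 16.7 to 41.7 points, the genic share of peak bases over 95.1% to 95.7%, and the marked share of histone genes over 18.2% to 36.4%. Requiring 25% of the span to be covered left 11 sarcomere and 2 endothelial genes marked, neither called, 1 calcium handling, 3 smooth muscle and 4 imprinted genes, reversed in direction without a call, and a fibroblast minus liver difference of 20.8 points. Counting any covered base gave 18 calcium handling genes, now called higher, 12 endothelial genes, no longer called, 18 fibroblast genes, reversed without a call, and an endothelial minus neuronal difference of 45.8 points, now called. A −log10 q of at least 5 gave 7 cardiac transcription factors, reversed without a call, and a fibroblast minus liver difference of 16.7 points. The pooled list gave 11 fibroblast genes and 36.4% of histone genes, both reversed without a call. Without matching on length, the 7 calcium handling and 7 imprinted genes lay below the random mean. The mean covered share of smooth muscle markers, 14.4%, lay below its matched mean. Without a minimum gene length, 2 macrophage markers were marked and the list was no longer called.

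Scaling both replicates to the same mean reversed the replicate difference of housekeeping (−18.4 points), mitochondrial (−11.7), cell cycle (−9.68) and H3K36 methylation genes (−4.62). By construction 1 factor for every gene, on a share that cannot pass 100%, lowers the well covered lists most, so these signs are not read as a finding. Other differences kept their sign but changed side relative to matched lists, without a call. Epicardial (0.771), endothelial (2.36), erythroid (0.756), neural crest (0.259), liver (0.0350) and skeletal muscle genes (0.0912) went from below to above the matched mean. Imprinted genes (0.243) went from above to below it. Scaling also ended the call for macrophage (0.0922), neuronal (−0.347), lung (0.170) and noncardiac transcription factor genes (0). The correlation of signal was 0.378 over wide peaks and 0.532 with −log10 p. Joined at 1 kb, there were 35033 domains, 2504 of at least 10 kb and 1 of at least 100 kb. With the main joining at 5 kb, 6 intergenic domains were at least 5 kb long. No paired analysis was possible because the samples formed a single group. The depth was unknown, so a gene without a peak cannot be said to lack the mark.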

Other observations

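The tests of sarcomere genes in this part, and that of X-linked housekeeping genes in replicate 1 against autosomal ones in replicate 2, were chosen only after the result was seen.

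The values here are for long non-coding genes of at least 2 kb that overlapped no protein-coding gene, unless said otherwise. Mir17hg, the host transcript of a microRNA cluster that acts in heart growth, was covered over 86.9% of its span (chromosome 14, 115042879 to 115046727), with 88.8% in replicate 1 and 44.8% in replicate 2. The small nucleolar RNA host genes Snhg17, Snhg1 and Snhg12 were covered to 72.7%, 67.8% and 50.6% (45.3%, 57.4% and 42.2% in replicate 2), and the nuclear RNA gene Malat1 to 49.2% (28.2% in replicate 2). They were chosen after their values were seen. Marked genes were rare among long intergenic RNA genes of at least 2 kb, at 2.19% of 4427, and at 0.848% of the 4009 that overlapped no protein-coding gene. Antisense RNA genes were marked in 15.8% of 2309 cases, and in 0.699% of the 143 that overlapped no protein-coding gene.

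Few X-linked genes were marked. A lack of housekeeping genes on the chromosome was argued against as the whole cause. Of 44 X-linked housekeeping genes 22 were marked, against 29 of 31 autosomal ones, a difference of 43.5 percentage points (Fisher's exact p = 4.7e-05). The 2 lists were matched on neither expression nor length. Lower expression of the X-linked genes, which is part of gene content, was therefore not excluded. A loss of sensitivity no larger than that from replicate 1 to replicate 2 was also argued against: X-linked housekeeping genes were covered to 23.9% on average in replicate 1 and autosomal ones to 39.3% in replicate 2, a difference of −15.4 points (two-sided permutation p = 0.00114), though these lists were not matched on expression. A larger loss on the X chromosome was not tested and stays open. In replicate 1, 43 of the 44 X-linked housekeeping genes had at least 1 covered base. Their mean covered share was 23.9% in replicate 1 and 8.42% in replicate 2, against 55.9% and 39.3% for autosomal ones. Fewer X copies for each cell cannot be told apart from the other explanations: X peaks were not stronger than autosomal ones, with a median fold of 2.80 against 2.96 in replicate 1 (difference −0.161, below the 2.96 to 3.01 of random autosomal sets) and of 2.72 against 2.87 in replicate 2, but a background taken over the whole genome would itself lower the folds on X, and the background used was not stated. A candidate explanation, as a hypothesis, is transcription from 1 X chromosome only in female embryos. The X inactivation escape genes Ddx3x, Kdm5c, Eif2s3x and Kdm6a had a mean covered share of 41.2%, against 17.1% for the other X-linked housekeeping genes. The difference was 24.1 points (exact one-sided permutation p = 0.0160), though Kdm6a was covered to only 2.91%. These genes were matched on neither expression nor length, and the sexes were pooled. Some X-linked genes outside the escape set were covered at least as far as Kdm5c, its best covered member at 58.8%. Flna was covered to 69.2% and Maged1 to 58.8%, both chosen after their values were seen.

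Sarcomere genes had a lower covered share in replicate 2 than genes of like share in replicate 1. Lower depth of replicate 2 alone was argued against as far as matching allows, but not excluded, since the depth was unknown. The list was covered to 10.2% in replicate 2, −5.37 points from the 15.6% (95% range 13.8% to 17.4%) of lists matched on replicate 1 share, peak strength and length (permutation p = 2e-05, the smallest that 100000 lists can give). Without the match on peak strength the matched mean was 16.5%. At the full match housekeeping genes lay above their range, at 36.9% against 34.1% (range 31.6% to 36.7%, permutation p = 0.0365, adjusted 0.351). Such matching may therefore leave other sets of genes apart too. A lower share of cardiomyocytes in replicate 2 cannot be told apart from other differences between the pools: the fibroblast, endothelial, epicardial and smooth muscle lists together were 0.0217 points from their matched mean (4.12% against 4.10%, range 3.52% to 4.71%), which decides nothing. Calcium handling and ion channel genes (6.01% against 6.08%) and cardiac transcription factors (6.81% against 7.98%, permutation p = 0.0640) were not shown to fall below their matched lists. The unstated further input of each peak list and differences between the embryo pools stay open, untested.

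Zinc finger genes held most of the strongest peaks. Reads shared between neighbouring zinc finger genes were argued against as the whole cause of a higher mean fold in marked Zfp genes. The 62 marked Zfp genes with no other zinc finger gene within 1 Mb had a mean strongest fold of 4.79. Genes matched on the last exon's share of the span had 4.08 (95% range 3.86 to 4.32), a difference of 0.705 (permutation p = 2e-05, the smallest possible). Over all marked Zfp genes the values were 5.25 and 4.00 (range 3.90 to 4.12). The excess was thus smaller in genes without a neighbour, and a part played by neighbours was not excluded. The test compared mean folds, so it does not settle what put zinc finger genes among the strongest peaks. Among 250 marked Zfp genes the summit of the strongest peak lay in the last exon in 65.6%, against 37.1% (range 32.0% to 42.0%) of matched genes (permutation p = 2e-05, the smallest possible), so a mark centred on the last exon, which carries the zinc fingers, may be what sets these genes apart, as a hypothesis. Reads shared with zinc finger genes farther away were not tested. No biological explanation beyond this was tested.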
